A study of Homo sapiens with 48 samples.

How the data were processed

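Messenger RNA was sequenced from 48 libraries of human cell lines in 16 groups of 3, which form 3 experiments. IMR-90 is a line of fetal lung fibroblasts, and SK-MEL-103 is a melanoma line. Doxorubicin damages DNA through topoisomerase II and was given at 200 nM for 48 h to induce senescence, a lasting arrest of the cell cycle with secretion of inflammatory proteins. In each line a first experiment transfected small interfering RNAs (siRNAs) the day before doxorubicin: a negative control siRNA, siMFN1, siMFN2, both together (siMFN1+2) or siMAVS, with RNA taken on day 7. Proliferating cells with the control siRNA form a sixth group in each line. MFN1 and MFN2 are the mitofusins, GTPases that fuse outer mitochondrial membranes. MAVS is the adaptor on that membrane through which RIG-I and MDA5 signal to interferon and NF-kB. A further experiment, in IMR-90, kept cells 7 days from the start of doxorubicin and then gave MFI8 at 20 µM, BI at 10 µM or the solvent DMSO for 48 h, with RNA taken on day 9, beside proliferating cells in DMSO. Per the labels MFI8 was given to inhibit the mitofusins and BI to activate them. Both are known here by code name only, and no structure is given. Whether the replicates are separate cultures is not stated.

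RNA was extracted with silica columns, and libraries were made with a stranded poly(A) kit and 10 cycles of PCR. The deposited table holds raw counts for 48898 Ensembl genes, whole numbers with no normalization. For the upstream steps the authors name Trim Galore 0.6.7, STAR 2.7.10a, featureCounts without a version, and the GRCh38 genome. The annotation release, the strand setting of the counting and any filter are not stated. If reads were counted without regard to strand, a gene that overlaps another on the opposite strand would also hold its reads, so antisense transcripts are not interpreted. How reads that map to more than 1 place were treated is not stated either, so nuclear copies of mitochondrial genes are not given as genes. Symbols were found for 48679 of the identifiers, which leaves 0.122 % of counts without a symbol. SOD2 and TREX1, members of the fixed lists, were not analysed here. Positions are from GENCODE 29, which holds 46876 of the identifiers and may not be the release used for counting.

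Libraries held 15206115 to 79204217 counts. Depth followed the replicate number: 53390716 to 79204217 counts for number 1, 30176556 to 50828283 for number 2 and 15206115 to 31127306 for number 3, so each group holds 1 library of each number. There are no molecular identifiers, so PCR copies count as reads, and limits from counts cover counting error only. No pair of libraries of the same group was a copy of another: over 48 pairs the smallest chi-square per degree of freedom was 11.1. One SK-MEL-103 siMFN2 library has no number in its title and is taken as number 1 from its place in the series.

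Group values are CPM, counts relative to the TMM-scaled library size in the units of the edgeR function cpm, as mean ± SD with n = 3. Genes were tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1, 1.17.8 of data.table): filterByExpr, TMM, and a quasi-likelihood F test on all groups of 1 experiment, without a block for the replicate number. A gene is called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. This value is written as padj for genes and for lists, and other p are named. Log2 fold changes carry a standard error (SE), the fold change over the square root of F. There were 14 comparisons within experiments and 5 differences between the cell lines, each the effect in SK-MEL-103 minus that in IMR-90 in 1 fit of 36 libraries. Folds are not given for a group whose libraries hold 3 counts or fewer together.

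The following was fixed before the data were examined: the groups, comparisons, tests and alternatives, 17 gene lists, and the rule for naming genes. The rule names MFN1, MFN2 and MAVS in the siRNA comparisons, and CDKN1A, MKI67, IL6, CXCL8, IL1B, CCL2, IFNB1, ISG15 and CXCL10 in every comparison. It adds the 5 highest and 5 lowest fold changes among called genes with a mean log2 CPM of at least 2 and groups that do not overlap, and up to 2 highest and 2 lowest called members of each list. The text draws on the genes so named, except that results of some genes are not reported here, though they stay in every test and count. A gene from outside the rule is said to have been chosen after its values were seen. The lists are SASP (senescence-associated secretory phenotype) cytokines and chemokines, SASP proteases and growth factors, interferon-stimulated genes, cytosolic nucleic acid sensing, NF-kB targets, p53 targets, cell cycle and DNA replication, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, mitochondrial dynamics and mitophagy, the integrated and mitochondrial stress response, cholesterol biosynthesis, NRF2 and oxidative stress, lysosome, fibroblast matrix and contractile genes, the melanocyte lineage, and epithelial, endothelial and leukocyte markers. Lists were tested with camera on log2 CPM (prior count 2) at the preset correlation of 0.01, again with the correlation estimated, and with fry. Beside the members called over all genes, the count adjusted over the list alone is given. List medians were also computed with genes at 0 in a group set at a floor of 3 counts over the group. Of 238 combinations of comparison and list, 2 had such a member (mitochondrial dynamics with doxorubicin in IMR-90, SASP cytokines with doxorubicin in the compound experiment), and the shift of the median was 0 in both. These are comparisons within experiments, and the differences between lines were not checked in this way.

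Replicate numbers were taken to pair 2 groups where the deviations of the libraries from their group means correlated at 0.1 or more for every number, over genes with a mean log2 CPM of at least 3. This held for siMFN1, siMFN2 and siMFN1+2 in IMR-90, for siMFN1, siMFN1+2 and siMAVS in SK-MEL-103, for every comparison of the compound experiment, and for the differences between lines with siMFN1 and siMFN1+2. It failed for doxorubicin in both siRNA experiments and for siMAVS in IMR-90, and could not be judged for siMFN2 in SK-MEL-103, where only 2 numbered pairs exist. For the comparisons that pair, a fit with the replicate number as a block over the paired doxorubicin groups is given beside the planned test, and is called the blocked fit. It was chosen after the pairing was seen and before its calls were. The planned block over all groups of an experiment is given as well for the knockdowns, the compounds and the differences between lines. It called 0 genes in each of the 3 comparisons of compounds. The numbers also separate depths, so the block removes depth together with any shared day.

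Results were recomputed with RLE scaling, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), removal of the mitochondrially encoded genes, only the libraries of the comparison, the block, DESeq2 1.42.0, each library left out in turn, and, in IMR-90, a term for library numbers 19 to 35 against 89 to 93 or only the former. Tests on simulated data used the depths and dispersions of 3 comparisons with 200 changed genes. For siMFN1+2 in IMR-90 with simulated replicate effects, the planned test recovered 60 % of 2-fold and 92 % of 4-fold changes with 0 unchanged genes called, and the blocked fit 95 % and 100 % with 26 unchanged genes called, 11.8 % of its calls. For MFI8 the values were 57 % and 93 % with 1 unchanged gene called, and 99 % and 100 % with 27, 11.9 %. For siMFN1+2 in SK-MEL-103 the blocked fit called 15 unchanged genes, 7.14 % of its calls, and the planned test 1. Without simulated replicate effects the planned test called 19 unchanged genes in IMR-90 (12.1 % of its calls), 9 in SK-MEL-103 (4.62 %) and 12 for MFI8 (8.11 %), and DESeq2 called 43 (21.9 %), 19 (9.09 %) and 51 (23.5 %). Counts from the blocked fit and from DESeq2, and in part those of the planned test, can therefore hold more than 1 unchanged gene in 20.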

Results

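The data are messenger RNA counts from 48 libraries of IMR-90 fibroblasts and SK-MEL-103 melanoma cells, 3 libraries in each of 16 groups. They ask how silencing the mitofusins MFN1 and MFN2, or the adaptor MAVS, changes transcription in cells made senescent with doxorubicin, and how compounds given to inhibit (MFI8) or activate (BI) the mitofusins do so. Total counts per library ran from 15540397 to 79204217 in the IMR-90 siRNA experiment, from 18434699 to 71851091 in SK-MEL-103 and from 15206115 to 74970221 in the compound experiment. Values are CPM as mean ± SD over n = 3 libraries, and the p of genes are edgeR values adjusted over all genes tested. On GRCh38 the silenced genes are MFN1 (ENSG00000171109, chromosome 3, 179347692 to 179394931), MFN2 (ENSG00000116688, chromosome 1, 11980181 to 12013514) and MAVS (ENSG00000088888, chromosome 20, 3846799 to 3876123). The markers followed throughout are CDKN1A (chromosome 6, 36676460 to 36687339), MKI67 (chromosome 10, 128096659 to 128126385), IL6 (chromosome 7, 22725884 to 22732002), CXCL8 (chromosome 4, 73740506 to 73743716), IL1B (chromosome 2, 112829751 to 112836903), CCL2 (chromosome 17, 34255218 to 34257203), ISG15 (chromosome 1, 1001138 to 1014540) and CXCL10 (chromosome 4, 76021117 to 76023497), all protein-coding genes. IFNB1, which encodes interferon beta (chromosome 9, 21077105 to 21077963), held 9 counts over all 48 libraries, at most 2 in any library, so a difference in it was not detectable at this depth.

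In IMR-90 with the control siRNA, doxorubicin was compared with proliferating cells. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose from 317 ± 45.4 to 1993 ± 153 CPM (log2 fold change 2.65, SE 0.13, padj = 1.1e-08). MKI67, a marker of cycling cells, fell from 473 ± 15.5 to 21.8 ± 12.6 CPM (-4.45, SE 0.66, padj = 6.3e-05), and the lamin gene LMNB1 fell from 216 ± 31.1 to 7.45 ± 2.01 CPM (-4.86, padj = 4.6e-07). The secreted cytokines IL6 and CXCL8 rose from 5.58 ± 4.21 to 97.1 ± 41.5 CPM (4.12, padj = 0.00032) and from 6.27 ± 2.91 to 215 ± 108 CPM (5.07, padj = 0.0011). IL1B rose from 5.14 ± 2.83 to 69.7 ± 20.9 CPM (3.78, padj = 0.032), CCL2 from 13.97 ± 9.75 to 43.6 ± 21.9 CPM (1.64, padj = 0.0061) and the interferon-stimulated ISG15 from 8.88 ± 1.33 to 30.3 ± 15.1 CPM (1.77, padj = 0.00025). CXCL10, an interferon-induced chemokine, rose from 0.450 ± 0.275 to 13.8 ± 4.59 CPM (5.07, padj = 0.00066). Of 19077 genes tested, 5223 rose and 4654 fell, 3993 and 1993 of them by at least 2-fold. The call of IL1B was lost with 4 of the 6 libraries left out in turn (adjusted p up to 0.092, without the proliferating library numbered 2), and 13 other called genes named by the rule lost theirs at least once.

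The secretory lists rose with doxorubicin in IMR-90. Among 28 SASP cytokines and chemokines 19 rose and 2 fell (20 and 2 adjusted over the list alone; median log2 fold change 3.53, camera padj = 0.0036, adjusted p = 0.51 with an estimated correlation), including CCL20 (6.85), while CXCL12 fell (-3.52). Among 38 SASP proteases and growth factors 21 rose and 2 fell (the same counts adjusted over the list alone; padj = 0.00036, adjusted p = 0.38 with an estimated correlation). Of 30 p53 targets 25 rose and 0 fell, adjusted over the list alone as well (median 1.29, padj = 4.1e-11, and 0.025 with an estimated correlation), among them GDF15 (3.94) and BTG2 (2.96). All 40 cell cycle genes fell under both adjustments (-4.02, padj = 5e-25, adjusted p = 0.24 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 12 rose under both adjustments (1.85, padj = 3.4e-05, adjusted p = 0.51 with an estimated correlation), and their share of all counts went from 1.07 ± 0.242 % to 4.18 ± 0.654 %. Nuclear-encoded respiratory chain genes went the other way, with 1 of 48 up and 16 down under both adjustments (-0.20, padj = 0.024, adjusted p = 0.55 with an estimated correlation). Lysosomal genes rose (24 of 32 up and 1 down, 25 and 1 adjusted over the list alone; padj = 7.1e-07, adjusted p = 0.24 with an estimated correlation), FUCA1, a lysosomal fucosidase, most (4.07).

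Interferon-stimulated genes (16 of 45 up, 4 down) and NF-kB targets (12 of 25 up, 2 down; 13 and 2 adjusted over the list alone) passed camera at 0.045 and 0.032, with adjusted p = 0.62 and 0.55 with an estimated correlation. Among the first, CXCL11 rose (4.86) and OAS3 fell (-1.98). Matrix and contractile genes rose (12 of 30 up, 2 down, 10 and 2 adjusted over the list alone; padj = 0.011, adjusted p = 0.62 with an estimated correlation), with TGFBI at 2.36 and the collagen crosslinker LOX at 2.35. Cholesterol biosynthesis fell (1 of 25 up, 11 down, padj = 0.004, adjusted p = 0.51 with an estimated correlation). The stress response list held 4 of 34 up and 16 down (5 and 16 adjusted over the list alone; padj = 0.069): ATF3 rose by 3.16 while PHGDH, which opens serine synthesis, fell (-2.73). Of 24 NRF2 genes 3 rose and 11 fell (padj = 0.069), among them the quinone reductase NQO1, from 520.5 ± 222 to 66.0 ± 24.3 CPM (-2.98). Nucleic acid sensing held 2 of 20 up and 4 down (padj = 0.39), with the RNA sensor RIGI at 1.05 and the DNA sensor CGAS at -2.37. Mitochondrial dynamics held 6 of 29 up and 10 down (median -0.13, mean 0.10, padj = 0.39). Melanocyte genes (3 of 14 up, 3 down, padj = 0.82) and markers of epithelium, endothelium and leukocytes (6 of 14 up, 0 down, padj = 0.069) did not pass. The counts of these last 5 lists, and of interferon-stimulated genes and cholesterol biosynthesis, were the same adjusted over the list alone.

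Silencing MFN1 in doxorubicin-treated IMR-90 cells lowered its mRNA from 49.0 ± 12.2 to 7.31 ± 0.313 CPM (-2.74, SE 0.28, padj = 0.00098), while MFN2 stood at 159 ± 13.0 and 144 ± 3.44 CPM. The adhesion molecule ICAM1 fell from 261 ± 177 to 29.9 ± 12.5 CPM (-3.12, SE 0.53, padj = 0.011). The neutrophil chemokine CXCL1 fell from 50.0 ± 22.8 to 4.42 ± 3.43 CPM (-3.45, SE 0.79, padj = 0.044) and CXCL6 from 6.96 ± 5.87 to 0.744 ± 0.620 CPM (-3.13, padj = 0.049). The neural adhesion gene L1CAM (-3.52, padj = 0.02) and ANGPTL4, an inhibitor of lipoprotein lipase (-2.31, padj = 0.019), fell as well, and the transcription factor TFAP2A rose (2.29, padj = 0.036). The lysosomal enzyme NEU1 fell by 0.77 on the log2 scale (padj = 0.013), and the p53 target ZMAT3 rose by 0.70 (padj = 0.035). IL6 stood at 18.4 ± 10.9 against 97.1 ± 41.5 CPM and CXCL8 at 23.6 ± 17.7 against 215 ± 108 CPM without passing the planned test (padj = 0.09 and 0.12). Both passed in the blocked fit (-2.55, SE 0.46, padj = 0.0014, and -3.53, SE 0.60, padj = 0.00098). MKI67 was 58.2 ± 40.4 against 21.8 ± 12.6 CPM (padj = 0.25; blocked 1.35, SE 0.17, padj = 0.00015), and CDKN1A did not move (-0.03, SE 0.13, padj = 0.95).

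With siMFN1 113 genes rose and 189 fell, against 2843 and 2759 in the blocked fit, where all 302 genes were called again, and 315 and 409 with the block over all groups. SASP cytokines held 3 of 28 down (11 adjusted over the list alone; median -1.60, camera padj = 6e-07, adjusted p = 0.49 with an estimated correlation). NF-kB targets held 6 of 25 down (12 adjusted over the list alone; -0.70, padj = 8e-09, adjusted p = 0.46 with an estimated correlation). Interferon-stimulated genes held 0 of 45 called and 0 adjusted over the list alone (-0.44, padj = 0.002, adjusted p = 0.49 with an estimated correlation), and the blocked fit called 14 down and 1 up. SASP proteases and growth factors held 3 of 38 down (1 up and 5 down adjusted over the list alone; padj = 0.0091, adjusted p = 0.49 with an estimated correlation). No cell cycle gene was called, although the list moved up (0.74, padj = 9.8e-12, adjusted p = 0.49 with an estimated correlation), and the blocked fit called 35 of 39 up. The NRF2 list did likewise (0.48, padj = 8.5e-05, adjusted p = 0.49 with an estimated correlation; 16 of 24 up in the blocked fit). The total of 302 was 36 without the control library numbered 1, 176 without control 3, and 46, 120 and 45 without siMFN1 libraries 1, 2 and 3. Of 17 called genes named by the rule, only MFN1 kept its call with each library left out in turn.

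Silencing MFN2 lowered its mRNA from 159 ± 13.0 to 17.3 ± 1.69 CPM (-3.20, SE 0.12, padj = 1.6e-09), with MFN1 at 49.0 ± 12.2 and 59.6 ± 11.4 CPM. SERINC2, which encodes a membrane protein of the serine incorporator family, rose from 153 ± 28.5 to 379 ± 29.3 CPM (1.31, SE 0.17, padj = 0.0046) and the methyltransferase gene INMT from 4.60 ± 0.809 to 18.8 ± 0.941 CPM (2.03, padj = 0.049). BST1, an ectoenzyme of NAD metabolism, fell from 18.3 ± 2.79 to 4.04 ± 0.172 CPM (-2.18, padj = 0.044) and the AMP deaminase AMPD3 from 103 ± 19.4 to 40.7 ± 7.97 CPM (-1.34, padj = 0.012). IL6 was 25.3 ± 11.9 CPM (-1.93, padj = 0.22; blocked -2.09, SE 0.45, padj = 0.006), CXCL8 24.5 ± 13.4 CPM (-3.12, padj = 0.17; blocked padj = 0.0019) and CCL2 11.1 ± 1.62 CPM (-1.98, padj = 0.079; blocked -1.91, SE 0.21, padj = 0.00015). MKI67 stood at 42.6 ± 23.2 against 21.8 ± 12.6 CPM, and cell cycle genes had a median log2 fold change of 0.57. SASP cytokines held 0 of 28 called (15 down and 1 up adjusted over the list alone; median -1.69, camera padj = 1.8e-07, adjusted p = 0.30 with an estimated correlation). Interferon-stimulated genes held 0 of 45 called (8 down adjusted over the list alone; -0.62, padj = 8.6e-10, adjusted p = 0.30 with an estimated correlation). Mitochondrially encoded mRNAs held 0 of 13 (7 down adjusted over the list alone; -0.84, padj = 1.8e-07, adjusted p = 0.38 with an estimated correlation). The blocked fit called 19, 19 and 9 members of these lists down. By edgeR 18 genes rose and 25 fell (2399 and 2228 in the blocked fit, with 42 of the 43 called again, and 90 and 136 with the block over all groups), 2569 had an unadjusted p under 0.05, and DESeq2 called 306. The total of 43 was 2 and 99 without control libraries 1 and 2, and 3, 6 and 10 without siMFN2 libraries 1, 2 and 3, and of 10 called genes named by the rule only MFN2 kept its call throughout.

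Silencing both mitofusins in IMR-90 lowered MFN2 to 18.1 ± 2.00 CPM (-3.13, SE 0.12, padj = 2.2e-09) and MFN1 to 11.3 ± 4.999 CPM (-2.08, SE 0.27, padj = 0.002). MT-ND5, a mitochondrially encoded subunit of complex I, fell from 3421 ± 570.1 to 378 ± 152 CPM (-3.18, SE 0.40, padj = 0.0018). MT-CO1, one of complex IV, fell from 10164 ± 1413 to 1314 ± 626 CPM (-2.95, SE 0.38, padj = 0.002). Mitochondrially encoded genes held 0.736 ± 0.360 % of counts, against 4.18 ± 0.654 % with the control siRNA and 1.07 ± 0.242 % in proliferating cells. The chemokine CXCL8 fell from 215 ± 108 to 8.21 ± 6.34 CPM (-4.65, SE 1.03, padj = 0.04). IL6 fell from 97.1 ± 41.5 to 11.9 ± 5.27 CPM (-2.99, SE 0.69, padj = 0.045). CCL2 fell to 7.98 ± 1.57 CPM (-2.44, SE 0.46, padj = 0.018) and CXCL1 to 1.45 ± 0.802 CPM (-4.98, padj = 0.013). ICAM1 fell to 26.2 ± 11.8 CPM (-3.30, padj = 0.0077). The interferon-stimulated OAS1, which senses double-stranded RNA, and BST2, which tethers virions, fell by 3.95 and 3.53 on the log2 scale (padj = 0.043 and 0.018). PRPS1, an enzyme of nucleotide synthesis, rose from 63.6 ± 28.4 to 187 ± 21.9 CPM (1.56, padj = 0.022). CXCL10 (-3.60, padj = 0.051), IL1B (-2.74, padj = 0.31) and ISG15 (-0.87, padj = 0.15) passed only in the blocked fit (padj = 0.00092, 0.0012 and 0.016), and CDKN1A was 2301 ± 47.0 CPM (0.21, SE 0.13, padj = 0.45). MKI67 stood at 39.8 ± 22.9 against 21.8 ± 12.6 CPM, and cell cycle genes had a median log2 fold change of 0.35.

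Of 13 mitochondrially encoded mRNAs 12 fell with siMFN1+2 (13 adjusted over the list alone; median -2.67, camera padj = 9.5e-29, adjusted p = 0.066 with an estimated correlation), and 13 did in the blocked fit. Nuclear-encoded respiratory chain genes had a median of 0.04 with 0 of 48 called and 0 adjusted over the list alone (padj = 0.14). Of 28 SASP cytokines 6 fell (16 adjusted over the list alone; -1.75, padj = 1.7e-10, adjusted p = 0.15 with an estimated correlation). Of 45 interferon-stimulated genes 6 fell (30 adjusted over the list alone; -1.06, padj = 2.6e-17, adjusted p = 0.085 with an estimated correlation). Of 25 NF-kB targets 7 fell (15 down and 1 up adjusted over the list alone; -0.94, padj = 2.9e-11, adjusted p = 0.085 with an estimated correlation). The blocked fit called 21, 31 and 18 of them down. By edgeR 122 genes rose and 178 fell (2704 and 2683 in the blocked fit, with 298 of the 300 called again, and 304 and 387 with the block over all groups). The total of 300 was 50, 538 and 144 without control libraries 1, 2 and 3, and 44, 127 and 79 without siMFN1+2 libraries 1, 2 and 3. MT-ND5, MT-CO1, ICAM1, MFN1 and MFN2 kept their calls with each library left out in turn. IL6 and CXCL8 lost theirs with 5 of the 6, with p up to 0.18 (without siMFN1+2 library 3) and 0.17 (without siMFN1+2 library 1).

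**Figure D1:**
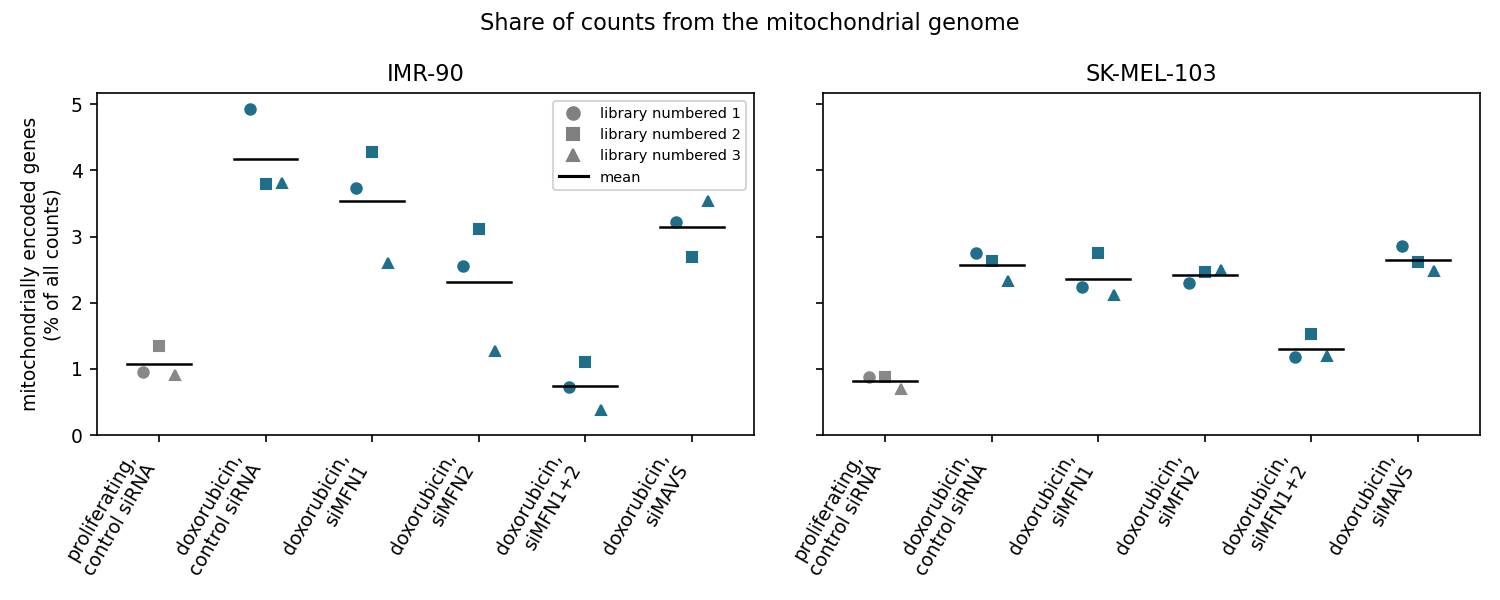
Share of all counts that fell on mitochondrially encoded genes (percent) in each library of both siRNA experiments, where circles, squares and triangles are libraries numbered 1, 2 and 3 (the SK-MEL-103 siMFN2 circle is the library without a number) and black lines are group means. In IMR-90 the mean is 4.18 % with doxorubicin and the control siRNA and 0.736 % with siMFN1+2, and in SK-MEL-103 the means are 2.57 % and 1.30 %.

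Silencing MAVS in IMR-90 lowered its mRNA from 123.3 ± 19.9 to 43.0 ± 5.17 CPM (-1.52, SE 0.16, padj = 0.0011), with MFN1 and MFN2 at 59.5 ± 5.34 and 166 ± 18.1 CPM. CXCL1 fell from 50.0 ± 22.8 to 2.94 ± 3.37 CPM (-4.10, SE 0.82, padj = 0.039). CXCL6 (-3.68, padj = 0.048) fell as well. IFI44L went from 1.57 ± 0.694 to 0.193 ± 0.123 CPM (-2.93, padj = 0.013) and XAF1 from 10.7 ± 6.30 to 2.28 ± 0.949 CPM (-2.22, padj = 0.049). PTX3, a secreted pattern recognition protein, fell from 264 ± 202 to 50.9 ± 24.1 CPM (-2.37, padj = 0.048). The adhesion genes DSG2, a desmosomal cadherin, and PCDH10, a protocadherin, fell by 3.95 and 3.42 on the log2 scale (padj = 0.004 and 0.0065). SERINC2 rose from 153 ± 28.5 to 381 ± 48.0 CPM (1.32, padj = 0.0031). IL6 was 29.2 ± 24.6 CPM (-1.73, SE 0.65, padj = 0.22), CXCL8 26.9 ± 28.3 CPM (-3.00, SE 0.95, padj = 0.15), ISG15 22.2 ± 9.78 CPM (-0.44, padj = 0.52) and CCL2 14.5 ± 5.56 CPM (-1.57, padj = 0.1). IL1B stood at 0.354, 96.6 and 48.8 CPM in siMAVS libraries 1, 2 and 3, against 91.5, 68.1 and 49.7 CPM in the controls, so only library 1 was far lower.

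SASP cytokines held 2 of 28 down with siMAVS (12 adjusted over the list alone; median -1.21, camera padj = 2e-07, adjusted p = 0.39 with an estimated correlation). Interferon-stimulated genes held 3 of 45 (20 adjusted over the list alone; -0.68, padj = 1.4e-12) and NF-kB targets 1 of 25 (10 down and 1 up adjusted over the list alone; -0.66, padj = 2.9e-06), the last 2 also with adjusted p = 0.39 with an estimated correlation. Mitochondrially encoded mRNAs had a median of -0.40 with 0 of 13 called under either adjustment (padj = 0.1). By edgeR 42 genes rose and 79 fell, 2875 had an unadjusted p under 0.05, and DESeq2 called 525. The total of 121 became 593 with a term for the range of library numbers, 409 with the block over all groups, 47 with no filter on low counts and 0 with only the libraries of the comparison. Library number and group partly run together here: all 3 siMAVS libraries belong to the earlier range of library numbers, while the control group has its library numbered 3 in the later one. The replicate numbers did not pair this group with its control. Over libraries numbered 19 to 35 alone siMAVS called 148 genes. The siMAVS library numbered 1 stood apart, with CXCL8 at 1.44 CPM against 57.3 and 21.8 CPM in libraries 2 and 3. The total of 121 was 22 and 231 without control libraries 1 and 2, and 73 and 33 without siMAVS libraries 2 and 3, and 13 of 18 called genes named by the rule lost their call at least once.

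The called genes of siMAVS and siMFN1+2 in IMR-90 overlapped: 25 rose in both and 37 fell in both, where independent lists of these sizes would share 0.269 and 0.737 genes. Both comparisons use the same control libraries. In 20 simulations of unchanged groups against shared controls the covariance of the log2 fold changes was 0.129 on average, against 0.199 in the data. The simulated libraries were independent, without effects shared by replicate number, so the excess cannot be read as sharing beyond the controls. At a minimum change of 1.5-fold in both the shared genes were 14 and 35. In SK-MEL-103 0 genes rose in both and 15 fell in both (independent lists would share 0 and 0.0371), with a covariance of 0.0372 against 0.0481 in simulation. The lowest simulated value there was 0.0451. Both knockdowns pair with the control by number in that line, which the simulation leaves out, so it gives no reference for unchanged groups. In the blocked fit 5 rose and 31 fell in both.

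**Figure D2:**
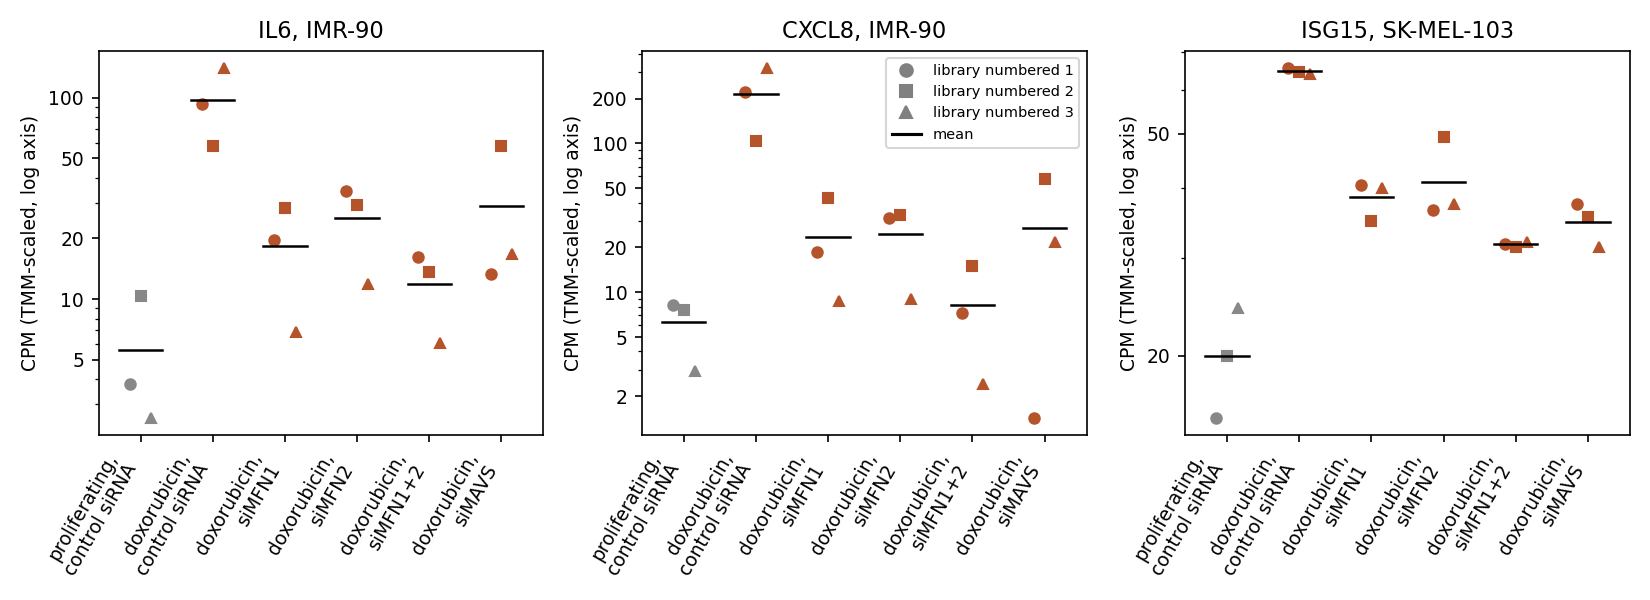
IL6 and CXCL8 in IMR-90 and ISG15 in SK-MEL-103 (CPM, logarithmic axes) in each library, where circles, squares and triangles are libraries numbered 1, 2 and 3 (the SK-MEL-103 siMFN2 circle is the library without a number) and black lines are group means. CXCL8 has means of 215 CPM with the control siRNA and 8.21 CPM with siMFN1+2, and ISG15 has means of 64.7 and 31.7 CPM.

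In SK-MEL-103 doxorubicin lowered MKI67 from 279.9 ± 80.9 to 0.478 ± 0.499 CPM (-9.52, SE 1.06, padj = 7.6e-07) and RRM2, which makes deoxyribonucleotides, from 387 ± 132 to 1.03 ± 0.494 CPM (-8.63, padj = 2.9e-08). CDKN1A rose from 562 ± 40.4 to 2169.6 ± 134 CPM (1.95, SE 0.12, padj = 3.7e-10). IL1B rose from 20.5 ± 3.90 to 101 ± 4.97 CPM (2.31, padj = 1.6e-09). IL6 and CCL2 rose at low levels, from 0.109 ± 0.0569 to 1.73 ± 0.195 CPM (3.82, padj = 1.1e-06) and from 1.11 ± 0.471 to 7.45 ± 2.67 CPM (2.60, padj = 0.00041). CXCL8 fell from 6.76 ± 2.93 to 3.63 ± 0.359 CPM (-0.88, padj = 0.011), a call lost without the proliferating library numbered 2 (adjusted p = 0.15). ISG15 rose from 19.9 ± 4.42 to 64.7 ± 0.776 CPM (1.72, padj = 2e-08) and IFI6, an interferon-induced protein, from 7.16 ± 1.60 to 70.9 ± 6.18 CPM (3.34, padj = 9.8e-11). CXCL10 was at or under 6 counts in every group and was not tested. Of 17945 genes tested 5355 rose and 5491 fell, and 7 of 74 called genes named by the rule lost their call with some library left out.

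All 40 cell cycle genes fell in SK-MEL-103 under both adjustments (median -5.02, camera padj = 1.9e-23, adjusted p = 0.19 with an estimated correlation, a value shared by the next lists unless given). Interferon-stimulated genes rose (29 of 38 up, 2 down, 30 and 2 adjusted over the list alone; 1.38, padj = 5.2e-07). So did p53 targets (22 of 29 up, 3 down, 23 and 3 adjusted over the list alone; padj = 1.4e-06) and mitochondrially encoded mRNAs (12 of 13 under both adjustments; 1.46, padj = 5.4e-06). Matrix genes rose as well (17 of 23 up, 1 down, 18 and 1 adjusted over the list alone; padj = 5.5e-05), COL5A1 from 29.2 ± 30.7 to 356 ± 53.6 CPM. Lysosomal genes rose (28 of 32 up, 3 down, 28 and 4 adjusted over the list alone; padj = 5.2e-07, and 0.011 with an estimated correlation), with the glucosidase GAA at 3.57 and the saposin precursor PSAP at 2.58. Cholesterol biosynthesis fell (1 of 24 up, 23 down under both adjustments; -1.42, padj = 4.3e-08). Nuclear-encoded respiratory chain genes fell (1 of 48 up, 36 down, 2 and 38 adjusted over the list alone; -0.46, padj = 1.3e-06). Unlike these, SASP cytokines held 7 of 19 up and 9 down under both adjustments (median -0.88, padj = 0.84), and NF-kB targets 7 of 21 up and 6 down (padj = 0.84).

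In doxorubicin-treated SK-MEL-103 cells siMFN1 lowered MFN1 from 54.6 ± 3.64 to 18.3 ± 3.75 CPM (-1.56, SE 0.16, padj = 0.00015) and left MFN2 at 98.0 ± 9.35 CPM against 100.1 ± 7.34. The interferon-stimulated IFI6 fell from 70.9 ± 6.18 to 17.7 ± 2.54 CPM (-2.00, SE 0.16, padj = 1.2e-05). IFIT1, which binds viral RNA, fell from 32.7 ± 7.01 to 10.3 ± 1.17 CPM (-1.67, padj = 0.0022). RSAD2, which encodes the antiviral protein viperin, fell from 1.40 ± 0.471 to 0.257 ± 0.0235 CPM (-2.50, padj = 0.00054) and ISG15 from 64.7 ± 0.776 to 38.5 ± 3.10 CPM (-0.75, SE 0.14, padj = 0.035). Of 38 interferon-stimulated genes tested 13 fell (23 adjusted over the list alone; median -0.43, camera padj = 1.9e-32, and 0.010 with an estimated correlation). IL6 (2.24 ± 0.628 against 1.73 ± 0.195 CPM, padj = 0.9), IL1B (98.7 ± 10.9 against 101 ± 4.97 CPM, padj = 0.98) and CDKN1A (2168 ± 291 against 2169.6 ± 134 CPM, padj = 1) did not pass. WBP1L rose from 126 ± 1.75 to 170.1 ± 3.63 CPM (0.44, padj = 0.015). By edgeR 5 genes rose and 17 fell, 1028 had an unadjusted p under 0.05 and DESeq2 called 47. The blocked fit called 258 and 361, with all 22 again, and the block over all groups 57 in total. The total of 22 was 10 and 13 without control libraries 1 and 2 and 7 and 11 without siMFN1 libraries 1 and 2. ISG15 lost its call with each of the 6 libraries left out in turn (p up to 0.32, without siMFN1 library 2), while IFI6, IFIT1, RSAD2, IFI27 and MFN1 kept theirs. SASP cytokines held 0 of 19 called (1 down adjusted over the list alone; -0.21, padj = 0.025, adjusted p = 0.22 with an estimated correlation).

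Silencing MFN2 in SK-MEL-103 lowered it to 20.5 ± 0.718 CPM (-2.29, SE 0.11, padj = 2.3e-09). IFI6 fell to 24.6 ± 4.10 CPM (-1.52, SE 0.16, padj = 0.00018). IFIT1 fell to 12.2 ± 3.58 CPM (-1.40, padj = 0.02) and RSAD2 to 0.389 ± 0.203 CPM (-1.70, padj = 0.019). ISG15 was 41.0 ± 7.14 CPM (-0.66, SE 0.14, padj = 0.16), IL6 1.49 ± 0.421 CPM (padj = 1) and IL1B 93.8 ± 8.69 CPM (padj = 1). Of 38 interferon-stimulated genes 8 fell (22 adjusted over the list alone; median -0.50, camera padj = 1.3e-39, and 0.0043 with an estimated correlation). Cell cycle genes held 0 of 40 called (0 adjusted over the list alone; 0.45, padj = 1.1e-13, adjusted p = 0.44 with an estimated correlation), and MKI67 was 2.41 ± 2.82 CPM. By edgeR 1 gene rose, WBP1L (0.42, padj = 0.043), and 11 fell, 615 had an unadjusted p under 0.05, DESeq2 called 21 and the block over all groups 6. The total of 12 was 4, 4 and 7 without control libraries 1, 2 and 3 and 4, 5 and 4 without siMFN2 libraries 1, 2 and 3, and of 7 called genes named by the rule MFN2 and IFI6 kept their calls throughout.

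Silencing both mitofusins in SK-MEL-103 lowered MFN2 to 23.8 ± 3.38 CPM (-2.06, SE 0.11, padj = 1.1e-08) and MFN1 to 22.8 ± 4.13 CPM (-1.25, SE 0.16, padj = 0.00048). IFI6 fell to 13.4 ± 2.37 CPM (-2.43, SE 0.17, padj = 4.5e-07), IFIT1 to 6.37 ± 1.10 CPM (-2.33, padj = 4.7e-05), RSAD2 to 0.123 ± 0.0333 CPM (-3.57, padj = 2.8e-05) and ISG15 to 31.7 ± 0.385 CPM (-1.03, SE 0.14, padj = 0.00085). MT-CO3 fell from 2289 ± 219 to 815 ± 124 CPM (-1.49, SE 0.22, padj = 0.0029) and MT-CO1 from 7039 ± 602 to 2611 ± 491 CPM (-1.43, SE 0.16, padj = 0.00015), both subunits of complex IV. The choline transporter SLC44A1 rose from 119.7 ± 8.03 to 181 ± 20.0 CPM (0.60, padj = 0.033). Of 13 mitochondrially encoded mRNAs 8 fell (11 adjusted over the list alone; median -0.98, camera padj = 6.1e-39, and 0.0015 with an estimated correlation; in the blocked fit 11 fell, with adjusted p = 0.106 with an estimated correlation). Of 38 interferon-stimulated genes 14 fell (23 adjusted over the list alone; -0.57, padj = 7.2e-57, and 0.00084 with an estimated correlation), and nucleic acid sensing held 0 of 20 called (4 down adjusted over the list alone; -0.10, padj = 2e-05, and 0.011 with an estimated correlation). IL6, IL1B and CDKN1A had padj = 1. By edgeR 6 genes rose and 37 fell, 738 had an unadjusted p under 0.05 and DESeq2 called 68, and the blocked fit called 81 and 144, with all 43 again. The block over all groups called 54. The total of 43 was 24 and 27 without control libraries 1 and 2 and 22 without siMFN1+2 library 1, and SLC44A1, WBP1L and GNG7 were the called genes named by the rule that lost their call.

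Silencing MAVS in SK-MEL-103 lowered it from 177 ± 8.76 to 66.7 ± 20.4 CPM (-1.42, SE 0.15, padj = 0.00018). The interferon-stimulated IFI6 fell to 11.04 ± 0.688 CPM (-2.68, SE 0.17, padj = 2.4e-07). IFIT1 fell to 6.37 ± 1.62 CPM (-2.33, padj = 9.8e-05), IFI44L from 2.89 ± 0.790 to 0.196 ± 0.0753 CPM (-3.74, padj = 0.00018) and ISG15 to 34.7 ± 3.14 CPM (-0.89, SE 0.14, padj = 0.0059). Of 38 interferon-stimulated genes tested 13 fell (28 adjusted over the list alone; median -0.67, camera padj = 6.2e-59, and 0.00071 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.01 with 0 of 13 called under either adjustment (padj = 0.82). By edgeR 0 genes rose and 18 fell, 650 had an unadjusted p under 0.05 and DESeq2 called 27. The block over all groups called 23. The blocked fit called 10 and 57, with all 18 again, and there MKI67, at 3.34 ± 3.90 against 0.478 ± 0.499 CPM, passed (2.71, SE 0.33, padj = 0.003; planned padj = 1). The total of 18 was 11 without siMAVS library 1, and OAS3 alone of 7 called genes named by the rule lost its call.

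**Figure D3:**
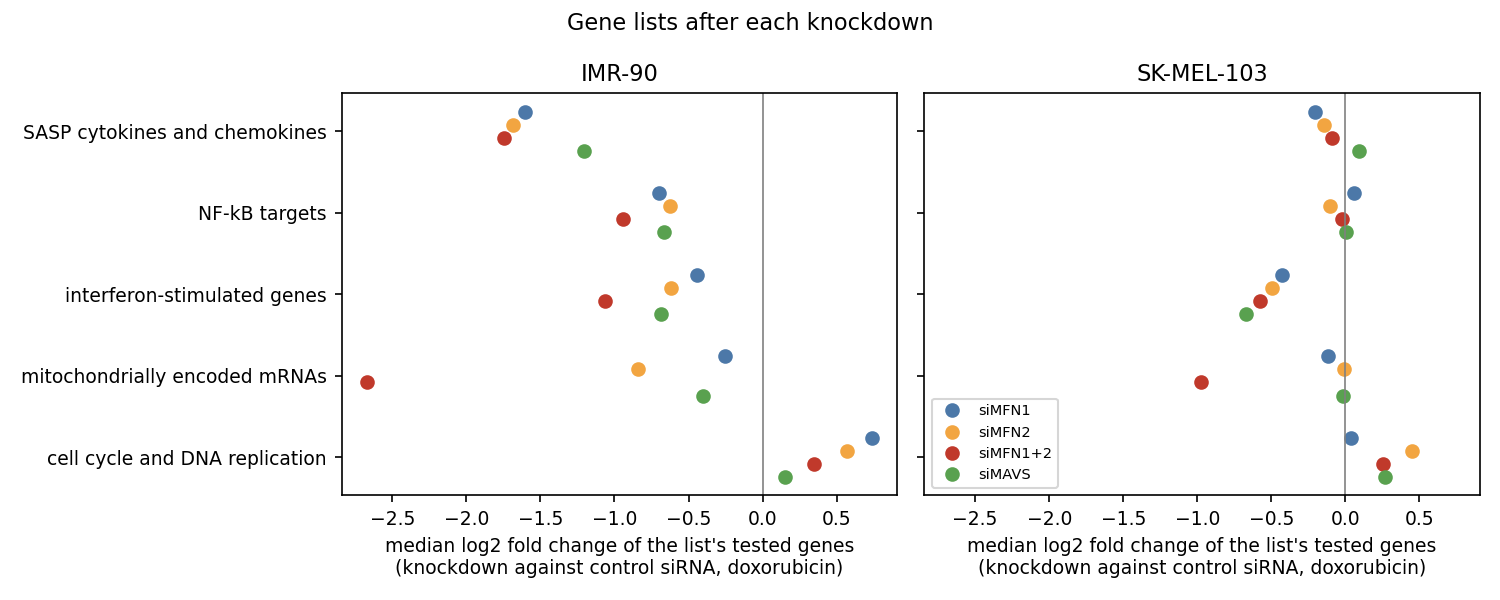
Median log2 fold change (horizontal axis, knockdown against control siRNA, both in doxorubicin) of the tested genes of 5 lists, with 1 point per knockdown and 1 panel per cell line. Mitochondrially encoded mRNAs lie at -2.67 in IMR-90 and -0.98 in SK-MEL-103 with siMFN1+2, and interferon-stimulated genes lie between -1.06 and -0.43 over the 4 knockdowns of both lines.

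The test of the difference between lines (effect in SK-MEL-103 minus effect in IMR-90) asked which of these responses differed. For doxorubicin CXCL8 differed by -5.86 (SE 1.07, padj = 0.00023), MKI67 by -4.93 (SE 1.30, padj = 0.0067) and CDKN1A by -0.61 (SE 0.16, padj = 0.0055), while IL6 did not pass (-0.21, SE 1.67, padj = 0.97). With siMFN1+2 the fall of mitochondrially encoded mRNAs was smaller in SK-MEL-103 (median difference 1.53, camera padj = 1.7e-24, and 0.035 with an estimated correlation; in the blocked fit adjusted p = 0.229 with an estimated correlation). MT-ND5 differed by 2.10 (padj = 0.026) and MT-ND4 by 1.83 (padj = 0.016). SASP cytokines had a median difference of 1.62 (padj = 5.5e-11, adjusted p = 0.085 with an estimated correlation). In SK-MEL-103 alone 19 of them passed the filter, against 28 in IMR-90. The joint fit also tests genes near the floor in SK-MEL-103, such as CXCL10, with 0 counts there with siMFN1+2. Part of the list's difference may therefore set falls in IMR-90 against genes at the floor. IL6 and CXCL8 stood at differences of 3.03 (SE 0.80) and 4.06 (SE 1.07), both with padj = 0.15 (blocked 3.15, SE 0.72, padj = 0.0084, and 4.33, SE 0.84, padj = 0.0028). MFN2 itself was lowered less in SK-MEL-103, by 0.91 with siMFN2 (padj = 0.017) and 1.05 with siMFN1+2 (padj = 0.0029; blocked 1.07, SE 0.14, padj = 0.00012). MFN1 stood at differences of 1.18 with siMFN1 (padj = 0.15; blocked 1.17, SE 0.22, padj = 0.0013) and 0.81 with siMFN1+2 (padj = 0.42; blocked 0.80, SE 0.21, padj = 0.019). Of 20892 genes tested 2724 were higher and 1914 lower for doxorubicin. With DESeq2's size factors these became 1893 and 2511, and the median of all genes was -0.13 rather than 0.026. The knockdowns gave 23 and 9 genes (siMFN1), 9 and 0 (siMFN2), 24 and 6 (siMFN1+2) and 8 and 1 (siMAVS) by edgeR. For siMFN1 and siMFN1+2 the blocked fit gave 1371 and 1486, and 1000 and 1206, with all 32 and all 30 called again. The block over all groups called 161, 7, 129 and 29 for siMFN1, siMFN2, siMFN1+2 and siMAVS. At an unadjusted p under 0.05 the siMFN2 difference held 1295 genes, and DESeq2 called 31. These counts hung on single libraries. For siMFN1 the total was 3 without IMR-90 control 1, 12 without IMR-90 siMFN1 library 1 or 3, 6, 15 and 17 without SK-MEL-103 controls 1, 2 and 3, and 9, 13 and 14 without SK-MEL-103 siMFN1 libraries 1, 2 and 3. For siMFN2 it was 3 and 26 without IMR-90 controls 1 and 2, 4 and 5 without IMR-90 siMFN2 libraries 1 and 3, and 4, 2 and 5 without SK-MEL-103 controls 1, 2 and 3. For siMFN1+2 it was 5 and 95 without IMR-90 controls 1 and 2, 9 and 16 without IMR-90 siMFN1+2 libraries 1 and 3, 5, 16 and 11 without SK-MEL-103 controls 1, 2 and 3, and 3, 14 and 17 without SK-MEL-103 siMFN1+2 libraries 1, 2 and 3. For siMAVS it was 4, 24 and 22 without IMR-90 controls 1, 2 and 3, 51 and 30 without IMR-90 siMAVS libraries 2 and 3, 4 without each SK-MEL-103 control in turn, and 5 without SK-MEL-103 siMAVS library 1.

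In the compound experiment doxorubicin with DMSO, 9 days after its start, again raised CDKN1A (from 415 ± 95.3 to 1912 ± 111 CPM; 2.20, SE 0.16, padj = 2.3e-06) and lowered MKI67 (from 507 ± 94.1 to 52.3 ± 27.6 CPM; -3.28, SE 0.59, padj = 0.00091). ISG15 rose from 8.48 ± 1.17 to 55.5 ± 31.2 CPM (2.71, padj = 0.0012), the interferon-induced IFI27 from 0.419 ± 0.101 to 17.6 ± 14.8 CPM (5.32, padj = 0.0065) and CCL2 from 8.06 ± 5.67 to 26.8 ± 8.47 CPM (1.67, padj = 0.015). IL6 stood at 95.7 ± 90.2 against 15.004 ± 18.2 CPM (2.63, SE 1.32, padj = 0.11) and CXCL8 at 158 ± 168 against 48.0 ± 52.0 CPM (1.71, padj = 0.31). Their spread followed the replicate number, with IL6 at 192.6, 14.1 and 80.5 CPM in DMSO libraries 1, 2 and 3, and both passed in the blocked fit (2.79, SE 0.41, padj = 0.0037, and 1.49, SE 0.33, padj = 0.014). IL1B passed in neither (padj = 0.47 and 0.18). The matrix proteoglycan DCN rose by 3.52 (padj = 0.0045) and the aldo-keto reductase AKR1C1 fell (-2.54, padj = 6.1e-05). CCL2 lost its call without the proliferating library numbered 2 (padj = 0.056), and 19 of the other called genes named by the rule lost theirs at least once.

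Interferon-stimulated genes rose (33 of 45 up, 0 down, 34 and 0 adjusted over the list alone; median 1.44, padj = 3.2e-05, adjusted p = 0.54 with an estimated correlation). So did p53 targets (26 of 30 up, 2 down under both adjustments; padj = 8e-08), 12 of 13 mitochondrially encoded mRNAs (1.62, padj = 3.1e-05) and lysosomal genes (26 of 32 up, 0 down, 27 and 1 adjusted over the list alone; padj = 5.5e-08), with adjusted p = 0.33, 0.35 and 0.14 with an estimated correlation. All 40 cell cycle genes fell (-3.05, padj = 8.7e-16, adjusted p = 0.33 with an estimated correlation). NRF2 genes fell (2 of 24 up, 14 down, 2 and 15 adjusted over the list alone; -0.83, padj = 0.0028, adjusted p = 0.43 with an estimated correlation). SASP cytokines held 7 of 29 up and 4 down (3 and 1 adjusted over the list alone; padj = 0.27). By edgeR 5495 genes rose and 5157 fell of 19056 tested, and 4884 and 4854 in the blocked fit. Over 18548 genes tested in both IMR-90 experiments, 3761 rose with doxorubicin in both, 3924 fell in both and 3 went opposite ways, where independent lists would give 1424, 1284 and 2705.

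With MFI8 against DMSO in doxorubicin-treated IMR-90 cells no gene passed the planned test: edgeR called 0 genes, 371 had an unadjusted p under 0.05, and DESeq2 called 0. The libraries paired closely by number (r of 0.89, 0.94 and 0.91 over genes, which are not independent replicates), and the blocked fit called 179 genes up and 390 down. The planned block over all groups, proliferating cells included, called 0, so the calls below rest on the fit chosen after the pairing was seen. The genes of the compound comparisons below were chosen after their blocked values were seen, apart from the markers. NRF2 targets rose in the blocked fit, 19 of 24 (23 adjusted over the list alone; planned median 0.53, camera padj = 4.7e-18, adjusted p = 0.081 with an estimated correlation, and 0.33 in the blocked fit). AKR1C1 rose from 24.0 ± 4.46 to 67.5 ± 33.0 CPM (1.44, SE 0.19, padj = 0.0017). NQO1 rose from 177 ± 152 to 339 ± 289 CPM (0.94, SE 0.06, padj = 5.3e-06) and the thioredoxin reductase TXNRD1 from 582 ± 149.6 to 976 ± 340.4 CPM (0.72, SE 0.05, padj = 2.6e-05), each higher in all 3 pairs. Matrix and contractile genes fell in the blocked fit, 16 of 29 (20 adjusted over the list alone; planned median -0.33, camera padj = 6e-09, adjusted p = 0.081 with an estimated correlation, and 0.38 in the blocked fit). Among them were smooth muscle actin ACTA2, from 419 ± 23.0 to 197 ± 81.8 CPM (-1.13, SE 0.21, padj = 0.012), the receptor PDGFRA (-0.76, SE 0.08, padj = 0.00075) and collagen COL3A1 (-0.59, SE 0.11, padj = 0.01). MKI67 (-0.40, padj = 0.02) and CXCL10 (-0.54, padj = 0.012) fell and IL1B rose (0.44, padj = 0.01) in the blocked fit only, where IL6 (-0.13, SE 0.09, padj = 0.54), CXCL8 (0.47, SE 0.22, padj = 0.31) and ISG15 (-0.23, SE 0.09, padj = 0.22) did not pass. Cell cycle genes held 10 of 39 down in the blocked fit (19 adjusted over the list alone), among them PLK1 (-0.42, SE 0.07, padj = 0.0095) and the cyclin CCNB1 (-0.40, SE 0.06, padj = 0.0036), both lower in all 3 pairs. In the planned test this list had a median of -0.20 (camera padj = 0.0093, adjusted p = 0.96 with an estimated correlation), which turned with single libraries left out, from -0.72 (without MFI8 library 2) to 0.16 (without DMSO library 2). Mitochondrially encoded mRNAs made up 3.53 ± 0.949 % of counts, against 3.71 ± 1.09 % in DMSO.

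With BI against DMSO edgeR called 0 genes, 175 had an unadjusted p under 0.05 and DESeq2 called 0, while the blocked fit called 78 up and 157 down. The planned block over all groups called 0. MFI8 and BI share their DMSO libraries. Cell cycle genes fell in the blocked fit, 21 of 39 (34 adjusted over the list alone; planned median -0.48, camera padj = 4.1e-14, adjusted p = 0.69 with an estimated correlation, and 0.25 in the blocked fit). The planned call of the list was lost without BI library 1 (-0.20, padj = 0.069) or DMSO library 2 (-0.13, padj = 0.063). MKI67 fell from 52.3 ± 27.6 to 32.6 ± 20.6 CPM (-0.77, SE 0.08, padj = 0.0006). The spindle checkpoint kinase BUB1 (-0.78, SE 0.09, padj = 0.00076) and the mitotic kinase PLK1 (-0.71, SE 0.08, padj = 0.00048) fell too, each lower in all 3 pairs. NRF2 targets rose in the blocked fit, 9 of 24 (17 adjusted over the list alone; planned median 0.30, camera padj = 2.6e-08, adjusted p = 0.69 with an estimated correlation, and 0.25 in the blocked fit), with NQO1 at 0.61 (SE 0.06, padj = 0.00022) and the heme oxygenase HMOX1 at 0.80 (SE 0.13, padj = 0.0056). Of 45 interferon-stimulated genes 3 rose in the blocked fit (5 adjusted over the list alone), ISG15 (0.44, SE 0.09, padj = 0.032), IFI6 (0.72, padj = 0.011) and IFI27 (0.72, padj = 0.0072). The list had a planned median of 0.09 (camera padj = 0.0032, adjusted p = 0.93 with an estimated correlation), which turned to -0.19 without DMSO library 2 and to -0.14 without BI library 1. IL6 was 121 ± 109 against 95.7 ± 90.2 CPM (planned 0.34, SE 1.23, padj = 1; blocked 0.26, SE 0.09, padj = 0.27).

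MFI8 and BI were compared directly at unlike doses, 20 and 10 µM, for the same 48 h. EdgeR called 0 genes, 326 had an unadjusted p under 0.05 and DESeq2 called 0, and the blocked fit called 247 genes higher and 416 lower with MFI8. The planned block over all groups called 0. Interferon-stimulated genes were lower with MFI8 in the blocked fit, 18 of 45 (28 adjusted over the list alone; planned median -0.32, camera padj = 1.2e-07, adjusted p = 0.95 with an estimated correlation, and 0.42 in the blocked fit). The planned call of the list was lost without MFI8 library 2 (-0.07, padj = 0.75). ISG15 stood at 48.0 ± 30.1 against 71.5 ± 28.4 CPM (-0.67, SE 0.09, padj = 0.0024) and CXCL10 at 11.7 ± 9.73 against 21.2 ± 17.9 CPM (-0.83, SE 0.10, padj = 0.0011). IL6 was lower by the same fit (-0.39, SE 0.09, padj = 0.034). NRF2 targets were higher, 7 of 24 (14 adjusted over the list alone; planned median 0.20, camera padj = 7.6e-05, adjusted p = 0.74 with an estimated correlation, and 0.42 in the blocked fit), TXNRD1 by 0.41 (SE 0.05, padj = 0.0015) and AKR1C1 by 0.76 (SE 0.18, padj = 0.037). The planned NRF2 call was lost without BI library 1 (padj = 0.14) or MFI8 library 2 (padj = 0.75). Matrix genes were lower, 10 of 29 (19 lower and 1 higher adjusted over the list alone; planned median -0.25, camera padj = 1.8e-06, adjusted p = 0.36 with an estimated correlation, and 0.42 in the blocked fit), with PDGFRA at -0.79 (SE 0.08, padj = 0.00052). Of 39 cell cycle genes 9 were higher (25 adjusted over the list alone; planned median 0.31, camera padj = 8.1e-05, adjusted p = 0.95 with an estimated correlation, and 0.42 in the blocked fit). The planned median of this list turned with single libraries left out, from -0.22 (without MFI8 library 2) to 0.64 (without BI library 2). Planned p values of all markers in the 3 compound comparisons were 1, with SE from 0.16 (CDKN1A) to 1.55 (IL1B).

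**Figure D4:**
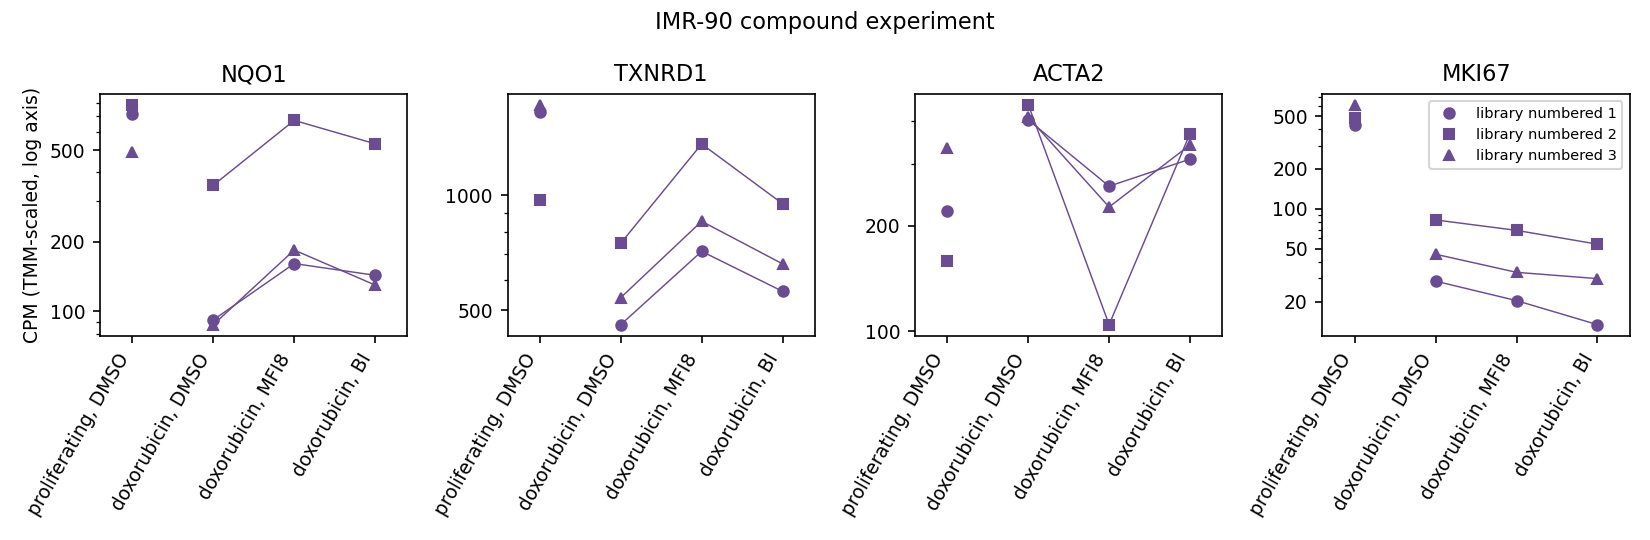
NQO1, TXNRD1, ACTA2 and MKI67 in each library of the compound experiment (CPM, logarithmic axes), where circles, squares and triangles are libraries numbered 1, 2 and 3 and lines join libraries of the same number among the doxorubicin groups. TXNRD1 has means of 582, 976 and 724 CPM with DMSO, MFI8 and BI, and MKI67 has means of 52.3, 40.9 and 32.6 CPM.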

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

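The tests of the difference between the lines were planned. The tests of cell mixing, nuclear copies, shared controls, sums of the single knockdowns and library range, and the splits of the libraries, were chosen after the results were seen.

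Results in this part stand out because the effect in SK-MEL-103 minus that in IMR-90 passed its test (edgeR for genes, camera for lists). For doxorubicin 4638 genes differed, and 32, 9, 30 and 9 did for siMFN1, siMFN2, siMFN1+2 and siMAVS. For each list the median over its genes of the line difference is given, which is not the difference of the list medians of the lines. The joint fit also tests genes near the floor in SK-MEL-103, where 19 SASP cytokines passed the filter alone, against 28 in IMR-90. For doxorubicin the values were -1.71 (SASP cytokines), -1.20 (SASP proteases and growth factors), 0.89 (interferon-stimulated genes), -0.36 (NF-kB targets), -0.20 (p53 targets), -1.24 (cell cycle) and -0.79 (cholesterol biosynthesis). For siMFN1 they were 1.30 (SASP cytokines), 0.35 (SASP proteases and growth factors), -0.23 (interferon-stimulated genes), 0.69 (NF-kB targets), -0.67 (cell cycle), -0.44 (NRF2) and 0.16 (lysosome). For siMFN2 the values were 1.03 (SASP cytokines), 0.31 (SASP proteases and growth factors), 0.50 (NF-kB targets), -0.17 (p53 targets), 0.75 (mitochondrially encoded mRNAs) and 0.15 (stress response). For siMFN1+2 they were 1.62 (SASP cytokines), 0.46 (SASP proteases and growth factors), 0.66 (NF-kB targets), 1.53 (mitochondrially encoded mRNAs), -0.063 (nuclear-encoded respiratory chain) and 0.23 (lysosome). For siMAVS they were 1.00 (SASP cytokines), 0.54 (SASP proteases and growth factors), 0.57 (NF-kB targets), 0.20 (cell cycle), -0.13 (nuclear-encoded respiratory chain) and -0.28 (NRF2). With an estimated correlation only the mitochondrially encoded mRNAs with siMFN1+2 still passed (0.035), a call that ended in the blocked fit (0.229), and the other 31 lists had values from 0.057 to 0.87.

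Among genes, doxorubicin differed for CXCL8 (-5.86), CDKN1A (-0.61), MKI67 (-4.93), OLFML2A (7.99), TNFRSF19 (5.15), AKR1C3 (4.13), SCG2 (3.86), SLC37A2 (3.61), TSPAN13 (-4.78), SPP1 (-4.57), RRM2 (-4.43), ETV5 (-3.51) and CYFIP2 (-3.29). With siMFN1 the genes were L1CAM (3.42), CHRNB1 (2.23), SERTAD4 (1.77), DDR1 (1.66), NT5E (1.40), GBP1 (-1.80), PUS7L (-1.10), NXPE3 (-0.96) and RIMOC1 (-0.66). With siMFN2 they were MFN2 (0.91) and TSPAN6 (1.16). With siMFN1+2 they were MFN2 (1.05), ZC3H12A (2.60), MT-ND5 (2.10), MT-ND4 (1.83), TMEM132A (1.87), GBP1 (-1.83), ANKRD46 (-1.02), EEA1 (-0.90) and RIMOC1 (-0.72), besides 1.96 for MTND1P23, a nuclear copy whose reads are not told apart from those of the mitochondrial gene. With siMAVS they were DSG2 (3.84), AMPD3 (1.72) and ANKRD46 (-1.05). MFN2 (siMFN1+2), DSG2 (siMAVS) and all 13 genes for doxorubicin kept their calls with each library left out in turn, and the others named here lost theirs at least once.

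For the line differences the labels were redrawn within each line, which tests no effect in either line and not an equal effect in both. A split that mixes the labels of 1 line keeps the effect of the other, so these splits leave open whether chance can be excluded for a line difference. Of 100 splits each, counting the real one, 4 gave at least as many genes as the real one for doxorubicin (real 3168, highest other 11086), 6 for siMFN1 (24 and 532), 4 for siMFN2 (3 and 13), 4 for siMFN1+2 (15 and 178) and 17 for siMAVS (5 and 1006). For the siRNAs they also break the pairing of libraries by number, seen in both lines for siMFN1 and siMFN1+2 (r over genes from 0.477 to 0.828), in IMR-90 for siMFN2 and in SK-MEL-103 for siMAVS. No split that keeps the pairs was run for the line differences, so the 2857 (siMFN1) and 2206 (siMFN1+2) genes of the blocked fit have none. Within an experiment 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real and the highest other count were 7866 and 0 (doxorubicin, IMR-90), 3 and 0 (siMFN1), 1 and 0 (siMFN2), 2 and 0 (siMFN1+2) and 0 and 0 (siMAVS). In SK-MEL-103 they were 9515 and 0, 33 and 387, 3 and 315, 61 and 0, and 7 and 0 in the same order. In the compound experiment they were 9562 and 0 for doxorubicin and 0 and 0 for the 3 comparisons of compounds. The split with 387 genes put controls 1 and 3 with siMFN1 library 3, and that with 315 put controls 1 and 2 with siMFN2 library 2. Splits that call many times the real number, as these do, point to a structure of the samples. These counts use only the 6 libraries concerned. Swapping the labels of 1 numbered pair in the blocked fit gave at most 9 genes, against real counts from 67 to 9738. These are 4 labelings with the real one, too few for a share under 0.05, so they do not exclude chance. A swap also turns an effect shared by the pairs into residual spread, which by itself lowers the count.

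The first pattern is the lower level of mitochondrially encoded mRNAs with siMFN1+2 in both lines (medians -2.67 and -0.98, adjusted p = 0.066 and 0.0015 with an estimated correlation, and -2.75 and -0.99 with 0.579 and 0.106 in the blocked fit). Cells that escaped the arrest are argued against: cell cycle genes put their share at up to 5.22 % in IMR-90 and 1.98 % in SK-MEL-103, where at least 107 % and 66.7 % would be needed. The share needed was taken over the 12 members called higher with doxorubicin in each line. Reads moving to nuclear copies are argued against as well, since the summed copies fell too, with changes of -1643 and -651 CPM. Against siMAVS the list stood at -2.17 and -0.94 (adjusted p = 0.0142 and 0.0119 with an estimated correlation, and in the blocked fit -0.96 with 0.346 in SK-MEL-103), and against the sum of the single knockdowns at -0.96 in SK-MEL-103 (0.0017) and at -1.48 in IMR-90, which stays open (0.195, and 0.518 in the blocked fit). An effect of losing both mitofusins beyond the sum of the single losses may explain the fall in SK-MEL-103, a hypothesis found and tested on the same data. It rests on the planned fit, since the pairing of siMFN2 could not be judged there and no blocked fit of the sum was run. The list's tests against the control siRNA and siMAVS in that line did not pass in the blocked fit. The lines were not compared for this excess, which was larger in IMR-90. In IMR-90 siMFN2 alone stood at -0.84 (camera adjusted p = 1.8e-07, and 0.38 with an estimated correlation).

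The second pattern is lower SASP cytokines and interferon-stimulated genes with all 4 siRNAs in IMR-90, where siMFN1, siMFN2, siMFN1+2 and siMAVS had 3, 0, 6 and 2 of 28 SASP cytokines and 0, 0, 6 and 3 of 45 interferon-stimulated genes called, and no list passed with an estimated correlation (adjusted p from 0.15 to 0.49 and from 0.085 to 0.49). Escaped cells are argued against for SASP cytokines, with a highest estimate of 10.9 % where the lowest library would need 51.8 %. For interferon-stimulated genes siMFN2, siMFN1+2 and siMAVS would need at least 49.5 %, against estimates of up to 8.14 %. With siMFN1 the lowest library would need 16.3 % against 10.9 %, too near to decide. The shares needed use only the 19 and 16 members called higher with doxorubicin. That choice uses the same control libraries and can raise the shares. For siMAVS the later range of library numbers stays open for the SASP cytokines as a list. SASP cytokines stood at -1.30 with the range as a term and -1.21 without, but the term is a shift shared by all groups. CXCL8 in the later library was 320 CPM against 221 and 104 CPM in the controls, and 8.78 against 18.7 and 43.2 CPM with siMFN1. It was also lower there with siMFN2, with siMFN1+2 and in proliferating cells. Such a term cannot remove a control library that stands high by itself. A control group that stands high by itself may explain part of the fall and cannot be told apart from a common effect of the siRNAs: siMFN1+2 against siMFN2, which leaves the controls out, gave -0.64 for SASP cytokines and -0.36 for interferon-stimulated genes (adjusted p = 0.602 and 0.347 with an estimated correlation). That test ignores the pairing by number. IL6 stood at 16.1, 13.6 and 6.02 CPM with siMFN1+2 in libraries 1, 2 and 3, against 34.6, 29.4 and 11.9 CPM with siMFN2. CXCL8, IL1B, CCL2, ISG15 and CXCL10 were also lower with siMFN1+2 in all 3 pairs. A high control group alone would not give these differences, which cover these markers only.

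The third pattern is lower interferon-stimulated genes with all 4 siRNAs in SK-MEL-103. Escaped cells are argued against, with a highest estimate of 2.03 % where the lowest library would need 43.6 %. The share needed uses the 29 members called higher with doxorubicin, chosen with the same control libraries. The shared control group may explain part of the fall and cannot be told apart from a common effect: siMFN1+2 against siMFN2 gave -0.20 (adjusted p = 0.218 with an estimated correlation). A second control siRNA was not analysed here.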

How the results depend on the processing

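The blocked fit and leaving out all libraries numbered 2 or 3 were chosen after seeing the data, and the other settings were planned. The cause was not tested for any change below, except where a setting has fewer libraries or tests more genes.

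No named gene called in the planned test or in the setting reversed its direction, and turns of genes called in neither were not counted. Over all fits with a library left out, 594 calls of named genes were lost, 2 were gained and 2944 results kept their status, called or not called. Calls lost were 53 with no filter on low counts, 101 with only the libraries of the comparison, which gained 1, 64 with libraries 19 to 35 alone, and 3 with RLE scaling. The blocked fit gained 44 and lost 3, the block over all groups gained 8 and lost 5, and DESeq2 gained 11 and lost 5. Of list results, 117 lost their call with an estimated correlation and 206 kept their status, called or not called. The numbers lost were 75 with fry, which gained 11, and 3 with RLE scaling, which gained 1. With a library left out 12 list results reversed, 115 calls were lost, 87 were gained and 2234 results kept their status, called or not called.

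The counts of called genes in the doxorubicin comparisons stayed within 1.5 times under each setting run. The balance of the line difference for doxorubicin did not: 2724 genes up and 1914 down became 1893 and 2511 with RLE scaling, 2090 and 2819 with DESeq2, and 1236 and 1932 with only the libraries of the comparison. The blocked fit called 5602, 4627 and 5387 genes for siMFN1, siMFN2 and siMFN1+2 in IMR-90, 619, 225 and 67 for siMFN1, siMFN1+2 and siMAVS in SK-MEL-103, 569, 235 and 663 for MFI8, BI and MFI8 against BI, and 2857 and 2206 for the line differences with siMFN1 and siMFN1+2. The block over all groups gave 724, 226, 691 and 409 in IMR-90 (siMFN1, siMFN2, siMFN1+2, siMAVS), 57 and 6 in SK-MEL-103 (siMFN1, siMFN2), and 161, 129 and 29 for the line differences (siMFN1, siMFN1+2, siMAVS), and 0 for each of the 3 comparisons of compounds, where only the blocked fit called genes. DESeq2 gave 810, 306, 777 and 525 in IMR-90, 47, 21 and 68 in SK-MEL-103 (siMFN1, siMFN2, siMFN1+2) and 175, 31, 114 and 59 for the line differences. With no filter the counts were 93, 17, 147 and 47 in IMR-90, and 12, 2, 20 and 9 for the line differences (siMFN1, siMFN2, siMFN1+2, siMAVS). In SK-MEL-103 they were 33, 11, 50 and 18, against 22, 12, 43 and 18 in the planned test.

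With only the libraries of the comparison edgeR called 3, 1, 2 and 0 genes in IMR-90. In SK-MEL-103 the counts went both ways, from 22 to 33 (siMFN1), 12 to 3 (siMFN2), 43 to 61 (siMFN1+2) and 18 to 7 (siMAVS). It called 24, 3, 15 and 5 for the line differences (siMFN1, siMFN2, siMFN1+2, siMAVS). The 0 stands beside 2875 genes at an unadjusted p under 0.05 with all libraries and 525 by DESeq2. Libraries 19 to 35 alone gave 68, 7 and 35 for siMFN1, siMFN2 and siMFN1+2, and the term for the range gave 710, 222, 686 and 593 in IMR-90. Without all libraries numbered 3, siMFN2 in SK-MEL-103 gave 5, and the cell cycle median with siMFN1 there turned to -0.12 (adjusted p = 0.0089).

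Leaving out 1 library at a time, counts ranged in IMR-90 from 36 (without control 1) to 300 (without control 2) for siMFN1, 2 to 99 for siMFN2 (controls 1 and 2), 44 (siMFN1+2 library 1) to 538 (control 2) for siMFN1+2 and 22 to 231 for siMAVS (controls 1 and 2). In SK-MEL-103 they ranged from 7 to 18 (siMFN1 libraries 1 and 3), 4 to 7 (siMFN2; controls 1 and 3), 22 to 32 (siMFN1+2 libraries 1 and 2) and 11 to 18 (siMAVS libraries 1 and 3). For the line differences they ranged from 3 to 48 (siMFN1; IMR-90 controls 1 and 2), 2 to 26 (siMFN2; SK-MEL-103 control 2 and IMR-90 control 2), 3 to 95 (siMFN1+2; SK-MEL-103 siMFN1+2 library 1 and IMR-90 control 2) and 4 to 51 (siMAVS; IMR-90 control 1 and siMAVS library 2).

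Medians of lists that turned with a library left out were, with MFI8, SASP cytokines from -0.68 (MFI8 1) to 0.91 (DMSO 1), cell cycle from -0.72 (MFI8 2) to 0.16 (DMSO 2), interferon-stimulated genes from -0.63 (MFI8 1) to 0.31 (DMSO 1) and the nuclear-encoded respiratory chain from -0.077 (MFI8 2) to 0.076 (DMSO 2). With BI interferon-stimulated genes ranged from -0.19 (DMSO 2) to 0.65 (DMSO 1), and for MFI8 against BI cell cycle ranged from -0.22 (MFI8 2) to 0.64 (BI 2). Others were cholesterol biosynthesis with siMAVS in IMR-90, from -0.15 (siMAVS 1) to 0.17 (siMAVS 2), cell cycle with siMFN1 in SK-MEL-103, from -0.31 (siMFN1 3) to 0.16 (siMFN1 1), and the line difference of cell cycle with siMAVS, from -0.075 (IMR-90 siMAVS 1) to 0.47 (IMR-90 siMAVS 3).

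Depth limits genes of low level: IFNB1 held 9 counts in all libraries together, and CXCL10 in SK-MEL-103 was not tested.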

Other observations

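The genes called with all 4 siRNAs and the comparison of MFI8 with siMFN1+2 were chosen after the values were seen.

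In IMR-90 7 genes rose and 7 fell with every siRNA, and in SK-MEL-103 0 rose and 8 fell. In IMR-90 SMC1A stood at 307 CPM in proliferating cells, 60.3 with doxorubicin and the control siRNA, and 100.4, 105, 100.9 and 104 with siMFN1, siMFN2, siMFN1+2 and siMAVS. NONO stood at 574, 220.2, 313, 329, 319 and 334 CPM in the same order, and AMPD3 at 14.1, 103, 43.2, 40.7, 39.7 and 37.1 CPM. CAT, which encodes catalase, stood at 48.6, 45.6, 64.6, 67.5, 70.0 and 65.6 CPM. Those of SK-MEL-103 include IFI6, IFI44L, RSAD2, IFIT1, OAS1, OAS2 and IFI27. The 4 comparisons of each line share their control libraries, so these genes are not 4 separate observations. The same libraries stand against proliferating cells, so a deviating control group alone would bring the knockdowns nearer to that level.

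If MFI8 acted like the loss of both mitofusins, the genes of the blocked siMFN1+2 comparison in IMR-90 might move the same way with MFI8. Over 5319 such genes 50.7, 46.3 and 54.6 % moved the same way in pairs 1, 2 and 3, a median of 50.7 %, and with BI 44.5, 44.5 and 55.7 % did. The question stays open, since the timing differs: siRNAs were given before doxorubicin, and MFI8 after 7 days of it. In the blocked fits 26 genes rose in both, 79 fell in both and 178 went opposite ways, where independent lists would give 26.0, 55.9 and 82.3.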
